A study of Arabidopsis thaliana with 24 samples.

How the data were processed

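Transcript levels were measured with Affymetrix arrays in cells of the developing Arabidopsis thaliana root epidermis from 8 mutant lines, with 3 arrays per line and 24 arrays in all. The lines carried cpc-1, egl3-1, gl3-1, myb23-1, try-82, ttg2-1 or wer-1 alone, or cpc-1 together with ttg2-1. Each line also carried a reporter in which the WEREWOLF promoter drives green fluorescent protein, which marks the developing epidermis and the lateral root cap. Per the labels' protocols, seedlings were grown for 5 days, roots were cut about 2 mm from the tip, their cell walls were digested, fluorescent cells were sorted, and total RNA was turned into biotin-labelled cRNA. Per the labels, the 3 arrays of a line are biological replicates. Wild type was not analysed here, so every comparison is between mutant lines.

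The authors deposited 1 table of log2 values, normalised with robust multi-array averaging (RMA) per the submitters' processing notes. The array type, the probe set definition and the software version are not given in the sources used here. The deposited log2 values ran from 2.01 to 13.6. RMA subtracts background, brings the arrays' distributions closer and sums probes per probe set, so a change shared by most transcripts would be reduced, and differences between dim genes are compressed. The deposited arrays were still not alike, with medians from 6.47 to 6.91 and interquartile ranges from 3.98 to 4.83. The 3 arrays labelled cpc ttg2 had the lowest medians. The number of arrays limits the precision. Detection calls were not used here, so the level at which a signal clears background is unknown, and low values are given without a claim that the transcript was present.

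The table held 21504 entries, 1 per locus code. The 64 control entries were left out of all tests, which left 21440 genes. Gene symbols came from a RefSeq gene table of assembly TAIR10.1, in which 21222 locus codes matched and 218 did not. Only names and neighbour order were taken from it. Symbols of the gene lists were fixed beforehand. A gene without a symbol is given by its locus code.

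A linear model with 1 mean per line was fitted to all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all lines shared 1 estimate of spread. The 6 comparisons were wer with cpc, the arrays labelled cpc ttg2 with cpc and with ttg2, gl3 with egl3, cpc with try, and wer with myb23. Differences are log2 of the first line minus the second, tests were 2-sided, and p-values were adjusted over the 21440 genes with the Benjamini-Hochberg (BH) method. A gene was called changed at a BH-adjusted p under 0.05. A moderated F test asked which genes differed among the 8 lines, and the same fit gave all 28 pairs of lines. Spreads are SD over 3 arrays for levels and SE of the fit for differences.

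Before the data were examined, the comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed. The rule took, per comparison, the 6 largest differences in each direction among called genes whose 3 arrays of 1 line all lay above the 3 of the other. It also took every measured member of the epidermal patterning list and the mutated genes, and up to 2 called members per direction from each other list. Other genes named in the text are said to have been chosen afterwards.

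The 14 lists held 268 genes, of which 242 were measured: root hair growth (30 of 34), root hair cell wall (24 of 26), epidermal patterning (13 of 15), lateral root cap (15 of 15), ground tissue (17 of 17), stele (15 of 15), cell cycle (20 of 25), iron deficiency (21 of 24), nutrient uptake (12 of 15), flavonoid synthesis (19 of 20), heat shock (12 of 12), wound, touch and jasmonate response (19 of 20), auxin response (18 of 18) and photosynthesis (7 of 12). Each list was tested in each comparison with camera, limma's competitive test, at a preset inter-gene correlation of 0.01, and BH-adjusted over the 84 tests. Of these, 36 passed, and 0 passed when the correlation was estimated from the residuals, so that adjusted p is printed beside each list that passed. The signs of mean, median and test differed for 8 lists that did not pass. These were iron deficiency and auxin response in the arrays labelled cpc ttg2 against cpc, nutrient uptake in gl3 against egl3, root hair wall in cpc against try, and lateral root cap, iron deficiency, nutrient uptake and auxin response in wer against myb23. Counts of called members are given over all genes and adjusted over the list alone. A root hair score per array was the mean, over the 54 measured members of both hair lists, of the log2 value minus the gene's mean. It was compared with exact 2-sided permutation tests, which cannot go below p = 0.1 with 3 arrays against 3.

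For each mutated gene, the mutant arrays were compared with the lines not mutated in it, a partial check of the labels, since a mutation need not lower its transcript. GL3 was not among the measured genes, so 6 of 7 could be read. TTG2 in the arrays labelled cpc ttg2 went the opposite way to that in ttg2, and they are called by that label throughout. Mitochondrially encoded transcripts, averaged per array, and the 25S rRNA control served as measures of RNA composition.

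Of the 6 comparisons, the replicate numbers paired the arrays only in wer with cpc, where deviations from the line means correlated at 0.44, 0.22 and 0.42 for replicates 1, 2 and 3, and 6 of 6 arrays lay closest to the array of their own number. The labels do not state this pairing, but the numbers in the sample descriptions run alongside it (1, 90 and S7 in wer, 3, 97 and S6 in cpc). For use as a block, these numbers were put in classes split at 50, with those that carry an S as a further class. The alternatives were a replicate block, the class of the number in the sample description as a block, only the 6 arrays compared, only genes above the median mean level, a further quantile normalisation, centring each array on its median, array weights, a trended and robust eBayes, a minimum log2 difference of 1, and leaving out each array in turn. Chosen after seeing the data were a fit without 4 arrays that stood apart (cpc replicate 3, cpc ttg2 replicate 3, ttg2 replicate 2 and egl3 replicate 2), the mitochondrial transcript level as a covariate, and array weights estimated gene by gene.

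The procedure was tested on simulated data. For wer against cpc over 21440 genes, it recovered 35% of genes with a simulated log2 change of 1 and 78% of those with a change of 2, and 9.6% of its calls were unchanged genes. For gl3 against egl3 with no simulated change it called 0 genes. The simulated noise was independent between genes and between arrays, unlike that of the real arrays, so these rates need not hold for them.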

Results

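Transcript levels of 21440 genes were measured on 24 arrays from sorted cells of the developing root epidermis of Arabidopsis thaliana, with 3 arrays for each of 8 mutant lines. The single mutants were cpc, egl3, gl3, myb23, try, ttg2 and wer, and the eighth line was labelled as the cpc ttg2 double mutant. In this tissue WEREWOLF (WER) and MYB23 are R2R3 MYB factors that act with the bHLH factors GL3 and EGL3 in the non-hair cells. CAPRICE (CPC) and TRIPTYCHON (TRY) are single-repeat MYB proteins that act in hair cell fate, and TRANSPARENT TESTA GLABRA2 (TTG2) is a WRKY factor. All values are log2 RMA levels, and each mean is given with its SD over n = 3 arrays. The median level per line ran from 6.49 ± 0.0324 (SD, n = 3) in the arrays labelled cpc ttg2 to 6.83 ± 0.0146 in egl3. The number of arrays limits the precision, and p-values measure the spread between these arrays.

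Of the 6 mutated genes with a measured transcript, TRY, TTG2 and CPC differed in the lines that carry their mutations. In the ttg2 arrays, TTG2 (AT2G37260) stood at 4.35 ± 0.44 (SD, n = 3), against a mean of 6.71 over the 6 lines without a ttg2 label, a difference of -2.37 (BH-adjusted p = 8.88e-05 over all genes, limma). In the arrays labelled cpc ttg2 it stood at 8.25 ± 0.54, which was 1.54 higher than the same 6 lines (adjusted p = 8.92e-05), a direction opposite to that in ttg2. A mutation need not lower its transcript, so a level that is not lower does not by itself contradict a label. Here, however, the lines labelled with the same ttg2 allele went opposite ways, and the directions given below for the arrays labelled cpc ttg2 carry this limit. CPC (AT2G46410) was lower (-0.72) in the cpc arrays and the arrays labelled cpc ttg2 together (adjusted p = 0.0042 over all genes and 0.00175 over the mutated genes). By line, the difference was -0.77 in cpc (adjusted p = 0.1) and -0.66 in the arrays labelled cpc ttg2 (adjusted p = 0.0285). CPC was as low in wer (9.85 ± 0.71) as in cpc (9.88 ± 0.47), so a lower level is not particular to lines with the cpc label. TRY (AT5G53200) was 1.94 higher in the try arrays (adjusted p = 0.00375). EGL3 in egl3, MYB23 in myb23 and WER in wer differed by 0.70, -0.54 and -0.16 with adjusted p of 0.0922, 0.0922 and 0.389 over the mutated genes, so none of these 3 passed as lower in its own line. Leaving out egl3 replicate 2 brought EGL3 past the threshold at 1.15 (adjusted p = 0.0265). Over both lines with the ttg2 label, TTG2 differed by -0.41 (adjusted p = 0.0656), and passed without cpc ttg2 replicate 1 (-0.50, 0.0375), cpc ttg2 replicate 2 (-0.48, 0.0496) or ttg2 replicate 3 (-0.51, 0.0344).

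**Figure D1:**
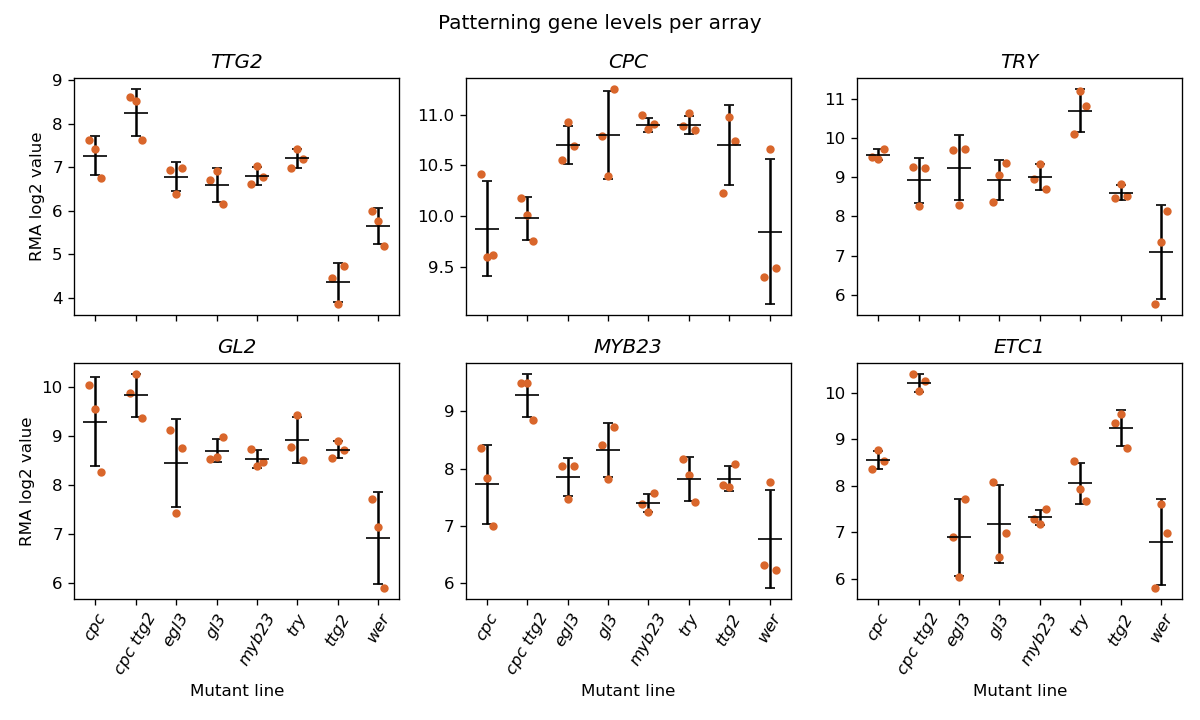
Log2 RMA levels of TTG2, CPC, TRY, GL2, MYB23 and ETC1 in the 8 lines, with 1 point per array and the mean and SD of 3 arrays. TTG2 averaged 4.35 in ttg2 and 8.25 in the arrays labelled cpc ttg2.

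Across all 8 lines, 5786 genes (27%) differed in the moderated F test at a BH-adjusted p under 0.05 (limma). The 28 pairs of lines gave between 0 and 7477 changed genes, with a median of 242. The 7 pairs that include the arrays labelled cpc ttg2 gave 1950 to 7477 genes (median 5576), and the other 21 pairs gave at most 1093 (median 141). The pair gl3 and myb23 gave 0 genes in limma. Without cpc ttg2 replicate 3, the F test passed 3588 genes.

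**Figure D2:**
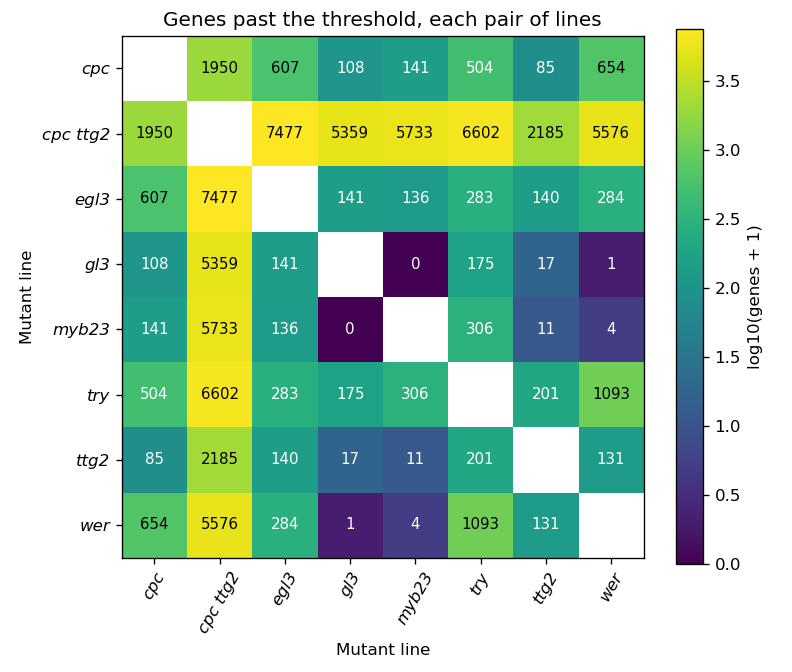
Number of genes with a BH-adjusted p under 0.05 for each of the 28 pairs of lines, with colour on a log10 scale of the count plus 1. The pairs with the arrays labelled cpc ttg2 gave 1950 to 7477 genes, and the other 21 pairs gave 0 to 1093.

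Between wer and cpc, lines that lack regulators with opposite roles in epidermal cell fate, 4 patterning genes were lower in wer and root hair genes were higher on average. Of the hair growth and hair wall lists, 8 of 30 and 2 of 24 genes passed, and neither list passed with an estimated correlation (adjusted p = 0.368 and 0.521). RHD6 (AT1G66470), a bHLH factor that starts root hair growth, was 2.33 ± 0.34 higher (SE, n = 3, 5.03-fold). GL2 (AT1G79840), the homeodomain factor that represses hair formation in non-hair cells, was lower (-2.36 ± 0.47), from 9.29 ± 0.91 in cpc to 6.92 ± 0.93 in wer. TRY and TTG2 were lower (-2.48 ± 0.48 and -1.61 ± 0.31) in wer. In all, 342 genes were higher and 312 lower in wer (BH-adjusted p under 0.05, limma), and 3519 genes had an unadjusted p under 0.05.

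Of the 30 measured root hair growth genes, 8 rose, 0 fell and 22 did not pass, with a mean difference of 1.37 (camera adjusted p = 2.57e-15, and adjusted p = 0.368 with an estimated correlation). Adjusted over the list alone, 23 were higher. Among them, RHD6 (adjusted p = 0.000856) and the receptor-like kinase MRH1 (AT4G18640, 2.34, adjusted p = 0.0189) had the largest differences. Of the 24 measured root hair wall genes, 2 rose, 0 fell and 22 did not pass (mean 1.05, adjusted p = 3.02e-07, and 0.521 as adjusted p with an estimated correlation). Adjusted over the list alone, 7 were higher. These 2 were RHS8 (AT1G63450) at 2.48 and COBL9 (AT5G49270), which is needed for oriented wall deposition in hairs, 4.58-fold higher. The root hair score averaged 0.81 ± 0.44 (SD, n = 3) in wer and -0.42 ± 0.62 in cpc, with no overlap of arrays (exact permutation p = 0.1, the smallest possible, and 0.3 after BH adjustment over 6 tests).

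Of the 13 measured patterning genes, 0 rose, 4 fell and 9 did not pass in wer (mean -0.72, adjusted p = 0.00367, and adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone, 1 was higher and 5 were lower. The 4 were GL2 (adjusted p = 0.008), TTG2 (0.0068), TRY (0.00708) and ETC1 (AT1G01380, -1.75, adjusted p = 0.035), a single-repeat MYB gene related to TRY. EGL3 differed by 1.48 with an adjusted p of 0.115 and MYB23 by -0.96 with 0.188. WER itself differed by -0.27 (adjusted p = 0.618) and CPC by -0.03 (0.97). TTG1, ETC2, SCM, JKD and PLDZ1 differed by -0.91 to 0.17 and did not pass.

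Auxin response genes were lower on average in wer, with 0 of 18 called higher and 4 lower (mean -0.79, adjusted p = 5.89e-06, and adjusted p = 0.242 with an estimated correlation), and 1 higher and 7 lower adjusted over the list alone. IAA13 (AT2G33310) fell by 2.75 and GH3.3 (AT2G23170), an auxin-conjugating enzyme, by 2.27. Of 19 wound, touch and jasmonate genes, 3 fell, 0 rose and 16 did not pass (mean -0.72, adjusted p = 2.03e-06, and adjusted p = 0.282 with an estimated correlation), with 6 lower adjusted over the list alone. JAZ8 (AT1G30135) and JAZ10 (AT5G13220), repressors of jasmonate signalling, were at -1.62 and -1.08. Of 15 lateral root cap genes, 1 fell, EXI1 (AT2G14095), at -1.66 (list mean -0.80, adjusted p = 8.96e-06, and adjusted p = 0.37 with an estimated correlation), and 4 were lower adjusted over the list alone. Flavonoid genes had 0 of 19 called (mean -0.55, adjusted p = 0.00679, and adjusted p = 0.488 with an estimated correlation) and 1 lower adjusted over the list alone. Heat shock genes had 0 of 12 called (mean 1.11, adjusted p = 7.91e-05, and adjusted p = 0.507 with an estimated correlation) and 6 higher adjusted over the list alone.

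The lists for ground tissue, stele, cell cycle, iron deficiency, nutrient uptake and photosynthesis did not pass, with means of -0.14, -0.13, -0.24, -0.12, -0.31 and 0.26 and adjusted p from 0.0969 to 0.599. Within them, the iron transporter gene IRT2 (AT4G19680) was 2.12 higher in wer, LHCB3 (AT5G54270) 1.19 higher and XCP1 (AT4G35350) lower (-0.90). The sulphate transporter gene SULTR1;2 (AT1G78000) was lower (-1.21) and the nitrate transporter gene NRT1.1 (AT1G12110) lower (-1.11).

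The largest differences over all genes were those of AT5G43030 (6.61), the cytochrome P450 gene CYP706A7 (AT4G12330, 6.14), AT5G51620 (6.13), AT4G02540 (6.07), AT5G51630 (5.46) and AT4G15390 (5.26), all higher in wer. AT2G15555 (-6.27), AT5G46670 (-4.94), AT2G45220 (-4.62), AT5G40960 (-4.14), FLS3 (AT5G63590, -4.09) and AT2G15760 (-3.71) were lower, each of the 12 with an adjusted p of at most 0.00322. In cpc, AT5G43030 stood at 2.36 ± 0.04, near the lowest value of the table, so its fold of 97.7 depends on a signal at the floor. CYP706A7, AT5G51620 and AT5G51630 were also low in cpc (3.13, 3.14 and 2.82), and AT5G46670 in wer (3.42). The lower means of the others ran from 4.07 to 5.97. CYP706A7 was also higher in the arrays labelled cpc ttg2 than in cpc (6.12) and in gl3 than in egl3 (6.10). A difference of this size in it was thus not particular to wer with cpc.

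The 3 arrays of wer and the 3 of cpc did not overlap for 18.4% of all genes, where chance gives 10%, and for 644 of the 654 called genes. Leaving out cpc replicate 2, cpc replicate 3, wer replicate 1 or wer replicate 3 lowered the count of 654 to 364, 221, 291 and 357. With the replicate numbers as a block, which pair these arrays, 761 genes passed, and 90 in a fit of only these 6 arrays. Without 4 arrays that stood apart, chosen after the data were seen, 279 passed and so did the cell cycle list (-0.52, adjusted p = 1.48e-05). Of 30 named calls, 16 held in each of the 6 runs that left out 1 array, among them RHD6, TRY, TTG2, EXI1 and the 12 largest. The root hair wall mean was 0.66 without cpc replicate 3, and the list still passed. MYB23 passed without wer replicate 2 (-1.46, 0.027), and GL2 ended without wer replicate 3 (-1.85, adjusted p = 0.0505). ETC1, RHS8, COBL9, IAA13 and SULTR1;2 ended without cpc replicate 2 or 3 or wer replicate 1 or 3, with adjusted p up to 0.188, 0.242, 0.22, 0.111 and 0.11. MRH1 ended without cpc replicate 3 or wer replicate 1 (up to 0.128) and IRT2 without these or wer replicate 3 (up to 0.176). JAZ10 ended without cpc replicate 1 or 3 or wer replicate 1 (up to 0.166), and JAZ8 also without wer replicate 3 (up to 0.13). XCP1 and LHCB3 ended without cpc replicate 2 or 3 or wer replicate 1 or 2 (up to 0.129 and 0.0911), and LHCB3 also without cpc replicate 1. NRT1.1 ended in each run except that without wer replicate 2 (up to 0.177), and GH3.3 in each except that without cpc replicate 1 (up to 0.184).

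**Figure D3:**
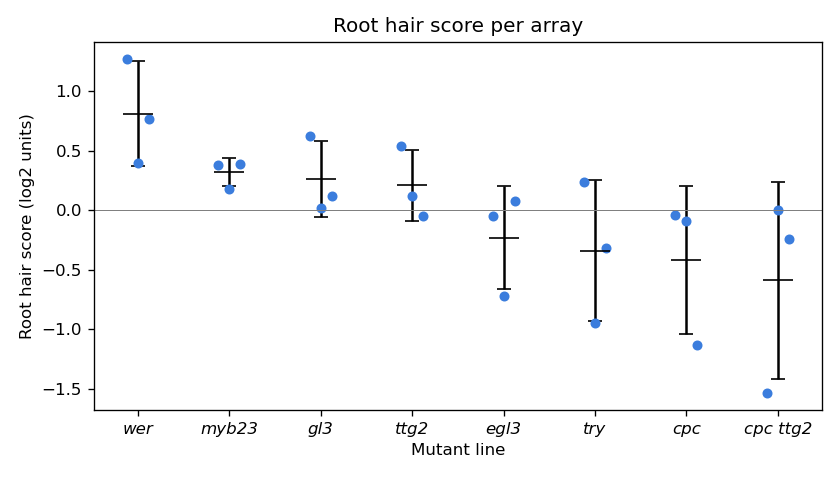
Root hair score of the 8 lines, the mean over 54 root hair genes of the log2 level minus the gene's mean, with 1 point per array and the mean and SD of 3 arrays. The means run from 0.81 in wer to -0.59 in the arrays labelled cpc ttg2.

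Between the arrays labelled cpc ttg2 and cpc, the pair that by its label shows what ttg2 adds to a cpc mutant, cell cycle genes were lower on average and heat shock genes higher in the arrays labelled cpc ttg2. Of these lists 7 of 20 and 6 of 12 genes passed, and neither list passed with an estimated correlation (adjusted p = 0.507 and 0.391). MYB23 (AT5G40330) and ETC1 were 1.55 ± 0.38 (SE, n = 3, 2.93-fold) and 1.68 ± 0.44 higher, and WER (AT5G14750) and TTG1 (AT5G24520), a WD40 protein that works with the MYB and bHLH factors, were lower (-0.83 ± 0.24 and -0.94 ± 0.22). TTG2 itself was 0.99 ± 0.31 higher (adjusted p = 0.052), where the label gives a ttg2 mutation in 1 of the lines. In all, 813 genes were higher and 1137 lower (BH-adjusted p under 0.05, limma), and 5357 had an unadjusted p under 0.05. A fit of only these 6 arrays passed 61 genes, 39 higher and 22 lower, so the count and the share of higher genes depend on the arrays fitted. Fewer degrees of freedom need not explain this, since the like fit of the arrays labelled cpc ttg2 with ttg2 passed 1478 genes. The lowest correlation of arrays within a line, 0.918, was in cpc, and the main fit uses 1 spread for all lines. The arrays labelled cpc ttg2 had higher means, untested, of mitochondrially encoded transcripts (6.85 ± 0.449, SD, n = 3, against 5.99 ± 1.09 in cpc), 25S rRNA signal (11.1 ± 0.194 against 8.84 ± 0.842) and the 3' to 5' differences of actin (5.79 ± 0.398 against 4.98 ± 0.244) and GAPDH (1.67 ± 0.128 against 1.09 ± 0.209).

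Of the 20 measured cell cycle genes, 7 fell, 0 rose and 13 did not pass (mean -1.03, camera adjusted p = 1.17e-07, and adjusted p = 0.507 with an estimated correlation), with 11 lower adjusted over the list alone. CDKB2;2 (AT1G20930), a mitotic kinase, was at -1.55 (adjusted p = 0.0131) and MCM7 (AT4G02060), a DNA replication factor, at -1.48 (0.0188). Of the 12 heat shock genes, 6 rose, 0 fell and 6 did not pass (mean 1.63, adjusted p = 3.93e-06, and adjusted p = 0.391 with an estimated correlation), with 9 higher adjusted over the list alone. The chaperone genes HSP90.1 (AT5G52640) and HSP17.6A (AT5G12030) were 3.05 (adjusted p = 0.000607) and 2.99 (0.0302) higher. The means of mitochondrially encoded transcripts and of the 25S rRNA were higher in the same arrays as those of the heat shock genes.

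Of the 13 patterning genes, 2 rose, 2 fell and 9 did not pass (mean 0.15, adjusted p = 0.664), with 3 higher and 2 lower adjusted over the list alone. ETC1 had an adjusted p of 0.024, MYB23 of 0.0176, WER of 0.0395 and TTG1 of 0.0153. GL2 and CPC differed by 0.55 (adjusted p = 0.512) and 0.10 (0.877). EGL3 and TRY differed by -0.91 (0.265) and -0.65 (0.436). Root hair wall genes had 1 of 24 higher and 3 lower (mean -0.57, adjusted p = 0.0272, and adjusted p = 0.778 with an estimated correlation), the same counts adjusted over the list alone. CSLD3 (AT3G03050), a cellulose synthase-like gene needed for hair growth, was 0.77 higher, and XTH13 (AT5G57540) and PRP1 (AT1G54970) were lower (-2.35 and -2.03). Root hair growth genes had 0 of 30 called (mean 0.14, adjusted p = 0.389). The root hair scores of -0.59 ± 0.83 and -0.42 ± 0.62 (SD, n = 3) overlapped (exact permutation p = 0.7, and 0.84 after BH adjustment).

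Markers of ground tissue and stele were higher on average, with 1 of 17 called (mean 0.58, adjusted p = 0.00257, and adjusted p = 0.507 with an estimated correlation) and 1 of 15 called (mean 0.46, adjusted p = 0.0109, and adjusted p = 0.282 with an estimated correlation). Adjusted over the list alone, 1 member of each was higher. The called members were EN7 (AT4G28100, 1.01) and the phloem regulator APL (AT1G79430, 1.31). In the lateral root cap list DMP4 (AT4G18425) was 1.38 higher and FEZ (AT1G26870) lower (-1.99). In the auxin list IAA14 (AT4G14550) and the auxin influx carrier gene AUX1 (AT2G38120) were 1.12 and 0.93 higher. These lists did not pass (adjusted p = 0.876 and 0.588), nor did iron deficiency (0.86), nutrient uptake (0.211), flavonoid (0.588), wound, touch and jasmonate (0.617) and photosynthesis genes (0.439).

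The largest differences were those of AT3G28320 (7.35), CYP706A7 (6.12), AT5G43030 (6.04), AT5G26270 (5.92), AT5G51630 (5.84) and AT5G43520 (5.28) on the higher side. On the lower side stood GSTU8 (AT3G09270, -5.30), JAL33 (AT3G16450, -5.01), AT3G11370 (-4.77), AT2G40010 (-4.06), AT1G54260 (-3.66) and VAMP728 (AT3G24890, -3.60). Each of the 12 had an adjusted p of at most 0.00115.

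Arrays did not overlap for 25.3% of all genes (10% by chance). With each array centred on its median, 1508 genes were higher and 838 lower, so the share of higher genes depends on the scaling. The count of 1950 became 726, 643, 775 and 982 without cpc replicate 1, cpc replicate 2, cpc ttg2 replicate 2 and cpc ttg2 replicate 3. Without cpc replicate 3 it was 2981. Of the 1950 genes themselves, 666, 635, 729, 849 and 1666 were still called in these runs. Of 29 named calls, 14 held in each of 6 runs, among them APL, HSP90.1 and the 12 largest. The root hair wall call ended without cpc replicate 1 (-0.30, adjusted p = 0.287), cpc replicate 2 (-0.45, 0.109) or cpc ttg2 replicate 1 (-0.05, 0.847), and its mean was -0.96 without cpc replicate 3. The calls of root hair wall (-0.20, adjusted p = 0.636) and stele (0.28, 0.169) also ended with the mitochondrial covariate, chosen after the data were seen. Root hair growth passed without cpc replicate 2 (0.34, 0.0334) or cpc ttg2 replicate 1 (0.57, 0.00206). TTG2 passed without cpc ttg2 replicate 3 (2.46-fold, 0.0282). MYB23 ended without cpc or cpc ttg2 replicate 2 (adjusted p up to 0.0683), TTG1 without cpc replicate 1 or cpc ttg2 replicate 3 (0.0769) and CDKB2;2 without cpc replicate 1 or cpc ttg2 replicate 2 (0.0726). AUX1 ended without cpc replicate 1 or 2 (0.0758). XTH13 and PRP1 also ended without cpc ttg2 replicate 1 (0.0937 and 0.104), and IAA14 without this or cpc ttg2 replicate 2 (0.176). WER, CSLD3, FEZ and MCM7 ended without cpc replicate 1 or 2 or cpc ttg2 replicate 2 or 3 (up to 0.151, 0.122, 0.139 and 0.0952). ETC1, DMP4 and EN7 ended in each run except that without cpc replicate 3 (up to 0.0837, 0.157 and 0.0975), and HSP17.6A in each except that without cpc replicate 1 (up to 0.136).

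Between the arrays labelled cpc ttg2 and ttg2, the pair that by its label shows what cpc adds to a ttg2 mutant, root hair wall genes and cell cycle genes were lower on average and ground tissue markers higher in the arrays labelled cpc ttg2. Of these lists 8 of 24, 5 of 20 and 5 of 17 genes passed, and none of the lists passed with an estimated correlation (adjusted p = 0.579, 0.513 and 0.29). TTG2 was 3.90 ± 0.31 higher (SE, n = 3, 15-fold, adjusted p = 1.88e-07), although both lines carry the ttg2 label. MYB23 was 1.46 ± 0.38 higher (adjusted p = 0.0204) and TTG1 lower (-0.85 ± 0.22, adjusted p = 0.0206). In all, 864 genes were higher and 1321 lower (BH-adjusted p under 0.05, limma), and 5781 had an unadjusted p under 0.05. Mitochondrially encoded transcripts averaged 6.85 ± 0.449 (SD, n = 3) in the arrays labelled cpc ttg2 and 6.24 ± 0.397 in ttg2. The 25S rRNA signal (11.1 ± 0.194 against 10.5 ± 0.448) and the 3' to 5' differences of actin (5.79 ± 0.398 against 4.86 ± 0.22) and GAPDH (1.67 ± 0.128 against 1.03 ± 0.403) also had higher means in the former, untested, so RNA quality may differ between these lines.

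Of 24 root hair wall genes, 8 fell, 0 rose and 16 did not pass (mean -1.04, camera adjusted p = 4.87e-05, and adjusted p = 0.579 with an estimated correlation), with 12 lower adjusted over the list alone. XTH13 and XTH26 (AT4G28850), which encode xyloglucan-modifying enzymes, were at -2.55 (adjusted p = 0.0124) and -2.22 (0.0122). Of 30 root hair growth genes, 1 fell, RHS15 (AT4G25220), at -2.18 (list mean -0.61, adjusted p = 0.013, and adjusted p = 0.757 with an estimated correlation), also 1 adjusted over the list alone. The root hair scores were -0.59 ± 0.83 and 0.21 ± 0.30 (SD, n = 3; exact permutation p = 0.2, and 0.3 after BH adjustment). Of 20 cell cycle genes, 5 fell, 0 rose and 15 did not pass (mean -0.98, adjusted p = 1.24e-06, and adjusted p = 0.513 with an estimated correlation), with 14 lower adjusted over the list alone. The cyclin genes CYCB1;4 (AT2G26760) and CYCA1;1 (AT1G44110) were at -1.53 and -1.24.

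Of 17 ground tissue genes, 5 rose, 0 fell and 12 did not pass (mean 0.95, adjusted p = 1.48e-05, and adjusted p = 0.29 with an estimated correlation), with 8 higher adjusted over the list alone. CASP1 (AT2G36100) and the peroxidase gene PER64 (AT5G42180), which act in the Casparian strip of the endodermis, were 2.22 and 1.76 higher. Stele markers had 2 of 15 higher, APL (1.45) and XCP1 (0.88), with 3 adjusted over the list alone (mean 0.40, adjusted p = 0.0248, and adjusted p = 0.333 with an estimated correlation). Heat shock genes had 2 of 12 higher, HSP101 (AT1G74310, 2.13) and HSP90.1 (1.91), with 2 adjusted over the list alone (mean 0.82, adjusted p = 0.0166, and adjusted p = 0.579 with an estimated correlation). Nutrient uptake genes had 1 of 12 higher, NRT1.1 (0.94), and 0 adjusted over the list alone (mean 0.42, adjusted p = 0.0462, and adjusted p = 0.568 with an estimated correlation).

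Of the 13 patterning genes, 2 rose, 1 fell and 10 did not pass, with the same counts adjusted over the list alone (mean 0.45, adjusted p = 0.249). GL2, ETC1, EGL3 and CPC differed by 1.11 (adjusted p = 0.134), 0.99 (0.152), -1.07 (0.168) and -0.67 (0.161). The flavonoid genes FLS1 (AT5G08640) and F3PH (AT5G07990) were 1.80 and 1.76 higher, IAA2 (AT3G23030) was 0.91 higher and IRT2 lower (-2.18). Their lists did not pass (flavonoid 0.07, auxin 0.391, iron deficiency 0.496 as adjusted p), nor did lateral root cap (0.629), wound, touch and jasmonate (0.116) and photosynthesis genes (0.818).

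The largest differences besides TTG2 were those of AT2G15555 (6.33), AT3G28320 (5.64), AT1G72900 (4.81), AT5G46670 (4.09) and AT2G15760 (4.02). On the lower side stood GSTU8 (-4.85), JAL33 (-4.71), AT2G40010 (-4.27), AT1G54260 (-4.03), AT3G11370 (-3.79) and ACLA-2 (AT1G60810, -3.70), a gene for a subunit of ATP-citrate lyase. Each had an adjusted p of at most 0.000856.

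Arrays did not overlap for 31.7% of all genes (10% by chance). With each array centred on its median, 1962 genes were higher and 925 lower, so the share of higher genes depends on the scaling. The count of 2185 became 951, 1225, 1230, 1451 and 822 without cpc ttg2 replicate 2, cpc ttg2 replicate 3, ttg2 replicate 1, ttg2 replicate 2 and ttg2 replicate 3. Of the 2185 genes themselves, 889, 1065, 1163, 1333 and 793 were still called in these runs. Of 30 named calls, 16 held in each of 6 runs, among them TTG2, XTH26, APL, HSP90.1, IAA2 and the other 11 largest. The root hair growth call ended without cpc ttg2 replicate 1 (-0.18, adjusted p = 0.659) or ttg2 replicate 1 (-0.43, 0.122), and its mean was -0.92 without cpc ttg2 replicate 2. The root hair wall mean was -0.52 without cpc ttg2 replicate 1 (adjusted p = 0.0311), where the difference in root hair score went from -0.80 to -0.33. The calls of root hair growth (-0.44, 0.115) and stele (0.27, 0.145) also ended with the mitochondrial covariate. JKD, at 0.95 (adjusted p = 0.104), passed without ttg2 replicate 2 (2.46-fold, 0.0493). Without cpc ttg2 replicate 1, XTH13 and IRT2 ended (0.0535 and 0.0516), and RHS15 without this or ttg2 replicate 1 or 3 (up to 0.132). MYB23 ended without cpc ttg2 replicate 1 or 2 or ttg2 replicate 1 or 2 (0.0759) and TTG1 without cpc ttg2 replicate 3 or ttg2 replicate 1 or 3 (0.106). HSP101 ended without cpc ttg2 replicate 2 or ttg2 replicate 1 (0.0826), XCP1 without cpc ttg2 replicate 3 or ttg2 replicate 3 (0.0778), PER64 without cpc ttg2 replicate 2 or ttg2 replicate 2 or 3 (0.0609) and F3PH without these or cpc ttg2 replicate 3 (0.104). CASP1 and FLS1 ended in each run except that without ttg2 replicate 1 (up to 0.129 and 0.166), and CYCB1;4, CYCA1;1 and NRT1.1 in each of the 6 runs (up to 0.153, 0.117 and 0.179).

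The difference that goes with cpc was compared on arrays that share none. Chromosome segments or RNA composition that both lines with the cpc label could share cannot be told apart from an effect of the cpc mutation here. The differences from wer and from try also hold the effects of those lines' own mutations. Across genes, cpc minus wer and the arrays labelled cpc ttg2 minus ttg2 correlated with Pearson r = 0.31 and Spearman rho = 0.30, and genes are not independent replicates. Higher in both were 82 genes, where 12.6 were expected from the separate counts, 35 were lower in both (21.1 expected) and 8 went opposite ways (33 expected). The 82 include TTG2 (1.61 and 3.90), whose second value carries the limit of the ttg2 label. For cpc minus try, r was 0.43 and rho 0.44, with 91 genes higher in both (13 expected), 38 lower in both (11.2 expected) and 13 opposite (27.2 expected). With the mitochondrial covariate, chosen after the data were seen, these r were 0.14 and 0.21, so part of the correlation went with that level. Without wer replicate 3 or cpc replicate 3, the r with wer was 0.192 and 0.195. The differences from wer and from try share the 3 cpc arrays, so genes called in both of them are not 2 separate findings. Among genes called the same way in all 3 differences, chosen by size after their values were seen, AT2G15555 (6.27, 6.33 and 7.13) and AT5G46670 (4.94, 4.09 and 5.20) led the higher genes. PROPEP1 (AT5G64900), the precursor of a defence peptide, was at 3.69, 2.61 and 2.54, and the brassinosteroid synthesis gene BR6OX2 (AT3G30180) at 1.55, 1.02 and 1.76.

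Between gl3 and egl3, lines mutated in related bHLH genes, no measured patterning gene passed the test. OPR3 (AT2G06050), an enzyme of jasmonate synthesis, was 2.63 ± 0.45 higher (SE, n = 3, 6.21-fold, adjusted p = 0.00423), at 11.07 ± 0.53 in gl3 against 8.43 ± 0.34 in egl3. CYP706A7 was 6.10 ± 0.40 higher, and SBT3.12 (AT4G21326), a subtilase gene, was lower (-4.35 ± 0.20). In all, 104 genes were higher and 37 lower (BH-adjusted p under 0.05, limma), and 1997 had an unadjusted p under 0.05. With the class of the sample number as a block it was 135 higher and 109 lower, so the share of higher genes depends on the model. GL3 was not among the measured genes, and EGL3 differed by -0.30 (adjusted p = 0.923). The 3' to 5' differences of GAPDH (1.94 ± 0.723, SD, n = 3, against 0.992 ± 0.28) and actin (5.41 ± 0.603 against 4.78 ± 0.638) had higher means in gl3, untested and without overlap of arrays for GAPDH, so RNA quality may differ between these lines.

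Of the 13 patterning genes 0 passed, also adjusted over the list alone (mean -0.03, camera adjusted p = 0.871). GL2 differed by 0.25, MYB23 by 0.47, TTG2 by -0.18 and ETC1 by 0.29. Of 19 wound, touch and jasmonate genes, OPR3 rose, 0 fell and 18 did not pass, with 2 higher adjusted over the list alone (mean 0.41, adjusted p = 0.0152, and adjusted p = 0.568 with an estimated correlation). Root hair growth and root hair wall genes had 0 of 30 and 0 of 24 called, also adjusted over the list alone. Their means of 0.51 (adjusted p = 4.68e-05, and adjusted p = 0.579 with an estimated correlation) and 0.46 (adjusted p = 0.00141, and adjusted p = 0.647 with an estimated correlation) passed as lists. The root hair scores were 0.26 ± 0.32 in gl3 and -0.23 ± 0.43 in egl3 (SD, n = 3; exact permutation p = 0.2, and 0.3 after BH adjustment).

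Heat shock genes had 0 of 12 called and 1 lower adjusted over the list alone (mean -0.79, adjusted p = 0.000147, and adjusted p = 0.507 with an estimated correlation). Flavonoid genes had 0 of 19 called, also over the list alone (mean 0.30, adjusted p = 0.0217, and adjusted p = 0.513 with an estimated correlation), and ground tissue genes 0 of 17 (mean 0.34, adjusted p = 0.0404, and adjusted p = 0.579 with an estimated correlation). Iron deficiency genes had 0 of 21 called and 1 higher adjusted over the list alone (mean 0.27, adjusted p = 0.0272, and adjusted p = 0.513 with an estimated correlation). Lateral root cap, stele, cell cycle, nutrient uptake, auxin and photosynthesis genes did not pass, with means of -0.07, 0.17, -0.19, -0.02, 0.08 and -0.11. In the fit without 4 arrays that stood apart, chosen after the data were seen, cell cycle (-0.56, adjusted p = 9.35e-06) and stele (0.22, 0.0442) passed, and flavonoid (0.18, 0.0938) and ground tissue genes (0.29, 0.0648) did not. Ground tissue (0.30, 0.112) and iron deficiency (0.21, 0.0732) did not pass with the mitochondrial covariate.

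The other largest differences were those of AT4G02540 (5.82), AT1G51430 (5.66), AT2G01090 (4.76), AT4G20480 (4.70) and CYP705A27 (AT1G50520, 4.70). Lower in gl3 were AT5G56380 (-3.37), GSTF14 (AT1G49860, -3.02), AT2G26630 (-3.01), AT4G19240 (-2.87) and AT4G18975 (-2.80). Of the 141 called genes, 44% lay on chromosome 4, 32.6% on chromosome 1 and 1.42% on chromosome 3.

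Arrays did not overlap for 11.8% of all genes, where chance gives 10%, and for 140 of the 141 called genes. Without egl3 replicate 2 and gl3 replicate 3, 91 and 81 genes passed, and 47 in a fit of only these 6 arrays. The root hair wall call ended without egl3 replicate 2 (0.18, adjusted p = 0.152) or gl3 replicate 1 (0.22, 0.229). Without egl3 replicate 2 the root hair growth mean was 0.29 (0.0236). The difference in root hair score of 0.49 was 0.24 without egl3 replicate 2. Of 13 named calls, 11 held in each of 6 runs. AT5G56380 ended without egl3 replicate 2 or 3 or gl3 replicate 2 or 3 (up to 0.0978), and GSTF14 in each run except that without egl3 replicate 3 (up to 0.232).

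Between cpc and try, lines mutated in related single-repeat MYB genes, auxin response genes were higher on average in cpc, while no patterning gene and no root hair list passed. In the auxin list 3 of 18 genes passed, and the list did not with an estimated correlation (adjusted p = 0.242). IAA5 (AT1G15580), an early auxin response gene, was 2.42 ± 0.35 higher (SE, n = 3, 5.36-fold, adjusted p = 0.000393), and GH3.3 was 2.45 ± 0.59 higher (adjusted p = 0.0279). The flavonoid hydroxylase gene F3PH was 1.73 ± 0.45 higher and the chaperone gene HSP18.2 (AT5G59720) lower (-1.54 ± 0.36). In all, 322 genes were higher and 182 lower (BH-adjusted p under 0.05, limma), and 3424 had an unadjusted p under 0.05.

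Of 18 auxin response genes, 3 rose, 0 fell and 15 did not pass (mean 0.65, camera adjusted p = 1.87e-05, and adjusted p = 0.242 with an estimated correlation), with 5 higher adjusted over the list alone. Of 19 flavonoid genes, F3PH rose, 0 fell and 18 did not pass, also 1 adjusted over the list alone (mean 0.54, adjusted p = 0.009, and adjusted p = 0.504 with an estimated correlation). Of 12 heat shock genes, HSP18.2 fell, 0 rose and 11 did not pass, with 2 lower adjusted over the list alone (mean -0.79, adjusted p = 0.0152, and adjusted p = 0.579 with an estimated correlation). Cell cycle genes had 0 of 20 called, also adjusted over the list alone (mean -0.46, adjusted p = 0.0171, and adjusted p = 0.732 with an estimated correlation). In the fit without 4 arrays that stood apart, chosen after the data were seen, the cell cycle mean was -0.18 (adjusted p = 0.386) and its call ended.

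Of the 13 patterning genes 0 passed (mean -0.08, adjusted p = 0.721), and 1, CPC, was lower adjusted over the list alone. TRY and CPC differed by -1.14 (adjusted p = 0.249) and -1.04 (0.0782), with no overlap of arrays for either, and GL2 by 0.38 (0.696). Root hair growth and root hair wall genes had 0 of 30 and 0 of 24 called, with means of -0.25 (adjusted p = 0.389) and 0.15 (0.414), the latter with a median of -0.02. The root hair scores were -0.42 ± 0.62 in cpc and -0.34 ± 0.59 in try (SD, n = 3; exact permutation p = 0.9, and 0.9 after BH adjustment). The lists for lateral root cap, ground tissue, stele, iron deficiency, nutrient uptake, wound, touch and jasmonate, and photosynthesis did not pass, with adjusted p from 0.0544 to 0.389.

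The largest differences were those of AT2G15555 (7.13), AT5G45500 (6.31), AT5G38020 (6.22), AT5G23830 (6.12), AT3G29035 (48.6-fold) and AT5G46670 (5.20) on the higher side. On the lower side stood AT5G51620 (-5.93), AT5G15360 (-5.40), AT5G19100 (-4.73), AT5G51630 (-4.47), AT1G65370 (-4.29) and AT5G41660 (-4.09). Each had an adjusted p of at most 0.0032.

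Arrays did not overlap for 18.3% of all genes (10% by chance) and for all 504 called genes. Without cpc replicate 3, try replicate 2 and try replicate 3, 271, 230 and 250 genes passed, and 215 in a fit of only these 6 arrays. Of 16 named calls, 13 held in each of 6 runs, IAA5 and the 12 largest. CPC passed without cpc replicate 1 (-1.31, 0.0353). F3PH ended without cpc replicate 2 or 3 or try replicate 2 or 3 (up to 0.201), HSP18.2 without cpc replicate 2 or 3 or try replicate 1 or 2 (up to 0.114), and GH3.3 in each run except that without cpc replicate 1 (up to 0.14). Root hair growth passed without cpc replicate 2 (-0.45, adjusted p = 0.0331) or try replicate 2 (-0.55, 0.00353), and root hair wall without cpc replicate 3 (0.53, 0.000892). Ground tissue genes passed without the 4 arrays that stood apart (0.45, 0.0089).

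Between wer and myb23, lines mutated in related R2R3 MYB genes, 4 genes differed, and both root hair lists were higher in wer on average. In them 0 of 30 and 0 of 24 genes passed, and neither list passed with an estimated correlation (adjusted p = 0.568 and 0.579). PRR7 (AT5G02810), a component of the circadian clock, was 1.70 ± 0.27 higher in wer (SE, n = 3, 3.26-fold, adjusted p = 0.0449). AT2G45220 was lower (-2.89 ± 0.37, adjusted p = 0.00449), TBL36 (AT3G54260) -2.98 ± 0.49 (0.0449) and RALFL32 (AT4G14010), a gene for a RALF-like peptide, -1.30 ± 0.22 (0.0473). Thus 1 gene was higher and 3 lower (BH-adjusted p under 0.05, limma), and 758 genes had an unadjusted p under 0.05. These 758 are less than a share of 0.05 of the 21440 genes tested, the share that chance alone would give. Their number is thus no sign of further differences. The main fit uses 1 spread for all lines, and the myb23 arrays correlated with each other at 0.9901 to 0.9926. Whether the shared spread is too wide for this pair was not tested.

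Root hair growth and root hair wall genes had 0 of 30 and 0 of 24 called, also adjusted over the list alone. Their means of 0.46 (camera adjusted p = 1.3e-06, and adjusted p = 0.568 with an estimated correlation) and 0.54 (adjusted p = 3.93e-06, and adjusted p = 0.579 with an estimated correlation) passed as lists. The root hair scores were 0.81 ± 0.44 in wer and 0.32 ± 0.12 in myb23 (SD, n = 3), with no overlap of arrays (exact permutation p = 0.1, the smallest possible, and 0.3 after BH adjustment). Of the 13 patterning genes 0 passed over all genes, and 4 were lower adjusted over the list alone (mean -0.57, adjusted p = 4.08e-05, and adjusted p = 0.242 with an estimated correlation). TRY, GL2, TTG2 and CPC differed by -1.91, -1.61, -1.15 and -1.07, each with an adjusted p of 0.999 over all genes. MYB23 and WER differed by -0.63 and -0.33, also with 0.999.

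Cell cycle genes had 0 of 20 called, also adjusted over the list alone (mean -0.51, adjusted p = 1.41e-06, and adjusted p = 0.513 with an estimated correlation). Heat shock genes had 0 of 12 called, also adjusted over the list alone (mean 0.33, adjusted p = 0.0379, and adjusted p = 0.641 with an estimated correlation). The lists for lateral root cap, ground tissue, stele, iron deficiency, nutrient uptake, flavonoid, wound, touch and jasmonate, auxin and photosynthesis did not pass, with adjusted p from 0.0544 to 0.86.

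Arrays did not overlap for 13.3% of all genes, where chance gives 10%. Without wer replicate 1, the means of root hair growth and wall were 0.29 (adjusted p = 0.000287) and 0.23 (0.0247), and the difference in root hair score went from 0.50 to 0.27. Without wer replicate 2, the wall mean was 0.83. None of the 4 calls held in each of the 6 runs that left out 1 array. Without myb23 replicate 3 or wer replicate 3, 0 genes passed in limma, and AT2G45220 had an adjusted p of up to 0.0807. PRR7, TBL36 and RALFL32 also ended without myb23 replicate 1 or 2 or wer replicate 1, with adjusted p up to 0.399, 0.41 and 0.581. In each of these 3 runs, 1 gene passed, and 0 in a fit of only these 6 arrays. The heat shock call ended with the replicate block (0.33, 0.0546) and without the 4 arrays that stood apart (0.33, 0.0594). Without wer replicate 2, which correlated with the myb23 arrays at r = 0.989 to 0.992 across genes and with wer replicates 1 and 3 at 0.973 and 0.970, 43 genes passed, among them CPC (-1.48, adjusted p = 0.036). A myb23 array was also the closest one to arrays of cpc, egl3, gl3 and ttg2, so this closeness was not particular to wer replicate 2. In that array GL2, TTG2 and TRY (7.14, 5.77 and 7.35) lay below all 3 myb23 arrays. Its MYB23 and CPC levels (7.76 and 10.66) lay nearer to myb23 than to the other wer arrays.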

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

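For the arrays labelled cpc ttg2, the tests with the mitochondrial covariate, of TTG2 in cpc and of the sample numbers were chosen after the result was seen. Those of neighbouring genes and of positions, with and without the covariate, were chosen before it was seen.

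The effect that goes with the ttg2 label on TTG2 itself differed between the cpc background and the others. TTG2 was -2.26 in ttg2 minus the 5 lines with intact CPC and TTG2, and 0.99 in the arrays labelled cpc ttg2 minus cpc, a difference of 3.24 ± 0.39 (SE, adjusted p = 1.12e-06 over the patterning list and 0.000131 over all genes, limma). Over all genes, 144 differed in this way.

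TTG2 was 1.54 ± 0.24 (SE) higher in the arrays labelled cpc ttg2 than in the 6 lines without a ttg2 label. With the mitochondrial transcript level as a covariate it was 1.94 ± 0.20 higher (adjusted p = 5.01e-06), which argues against that level as the whole cause. Other measures of RNA composition and quality were not fitted. In cpc, TTG2 was 0.66 higher than in the other 5 lines (95% interval 0.16 to 1.17), below the 1.65 ± 0.24 (SE) of the arrays labelled cpc ttg2. Compared directly, these arrays stood 0.99 ± 0.31 above cpc (adjusted p = 0.052 over all genes, limma), short of the threshold. The values lean against loss of CPC alone but do not exclude it. Whether these plants carried the ttg2 segment of the chromosome stays open, since only 1 gene among the 400 nearest to TTG2 separated ttg2 from the 6 lines, AT2G38330 (lower in ttg2, adjusted p = 0.0488). In the arrays labelled cpc ttg2 it differed the same way (-1.54), 1 of 1, and 1 gene cannot decide, so a wrong label and a change in TTG2 regulation in the double mutant cannot be told apart.

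Between the arrays labelled cpc ttg2 and cpc, 1950 genes differed (61 in a fit of only their 6 arrays), and these arrays lay at 71.6 to 128 on the first principal component (34.1% of the variance), above all others except cpc replicate 3 (90.5). With the mitochondrial covariate the count was 2509, and 1334 of the 1950 genes were still called. This argues against the mitochondrial transcript level as the whole cause, but not against RNA composition or quality in general. The 25S rRNA signal (10.86 to 11.24 against 8.036 to 9.715 in cpc) was not fitted. Neither were the 3' to 5' differences of actin and GAPDH, and none of these 3 measures overlapped between the lines. With the class of the number in the sample description as a block it was 1298, and 1076 of the 1950 were still called, while 2185 genes differed from ttg2, whose arrays are in the same class, which argues against the class as the whole cause. A batch particular to the arrays labelled cpc ttg2, which have the highest numbers (0 arrays of other lines have one as high), cannot be told apart from the genotype. The effect of the genotype, as labelled, stays among the open explanations, beside RNA quality and segments from different parental strains.

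The genes called between gl3 and egl3 lay close together on the chromosomes, with 44% of them on chromosome 4. Among measured genes 11 to 100 places away, there were 259 pairs of called genes where permuted positions gave 82.1, a ratio of 3.15 that 0 of 1000 permutations reached. Such a range argues against co-regulation of close neighbours as the whole cause, for which an excess within 10 genes (31 pairs against 9.33, ratio 3.32) would have been enough. With the mitochondrial covariate the ratio was 2.46, which argues against the mitochondrial transcript level as the whole cause. The pattern fits segments from different parental strains, a candidate explanation, and the parents of the lines are not given in the sources used here. This explanation may also apply to other comparisons, where the ratios at 11 to 100 places were lower (1.16 for wer with cpc, 1.43 for cpc with try). For the arrays labelled cpc ttg2, only genes with the lowest p were taken (493 against cpc, 497 against ttg2). The ratios there were 1.24 against cpc and 1.13 against ttg2. In each of these comparisons 0 of 1000 permutations reached the ratio, so an excess at this range was not particular to gl3 with egl3.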

How the results depend on the processing

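Under the alternatives run, no reported direction past its threshold reversed, and centring on the median or a further quantile normalisation left each total of the 6 comparisons within 1.5 times except wer with myb23 (2 genes after quantile normalisation). Centring moved the genes higher in the arrays labelled cpc ttg2 from 813 to 1508 against cpc and from 864 to 1962 against ttg2. Of 122 named gene calls, 48 ended on only the 6 arrays of the comparison, 34 without 4 arrays, 14 with the class of the sample number as a block, 9 with the log2 minimum of 1, 8 with centring, 5 after quantile normalisation, 3 with either kind of weights, and 4 each with the replicate block, the trended and robust eBayes and the mitochondrial covariate. The fit without 4 arrays, the mitochondrial covariate and the gene-by-gene weights were chosen after seeing the data. The alternatives without entries named as cross-hybridising and without mutated genes in the root hair lists were not run, because 0 entries and 0 members were of that kind. The names cannot show that no entry shares its signal with another. Among the genes called the same way in the cpc differences, AT4G10955 and UGE5 (AT4G10960) had the same values (1.54, 0.96 and 0.62). So did AT2G32235 and AT2G32240 (1.79, 1 and 0.8), so each pair may be 1 signal counted as 2 genes. Signal over background limits genes near the lowest value of the table. Why results changed between alternatives was not tested.

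The replicate block gave 761 genes for wer with cpc, the only comparison it pairs, 1 for wer with myb23, and 34 lists. Nutrient uptake in the arrays labelled cpc ttg2 against ttg2 (0.42, adjusted p = 0.0611), ground tissue in gl3 against egl3 (0.34, 0.0546) and heat shock in wer against myb23 (0.33, 0.0546) did not pass there, and flavonoid genes in the arrays labelled cpc ttg2 against ttg2 did (0.44, 0.0476). With trended and robust eBayes, wer with myb23 gave 1. Fits of only the 6 arrays of a comparison leave fewer degrees of freedom. They passed 90 genes for wer with cpc, and 61 and 1478 for the arrays labelled cpc ttg2 with cpc and with ttg2. For gl3 with egl3, cpc with try and wer with myb23 they passed 47, 215 and 0. Among genes above the median level, fewer were tested, and 78 (gl3 with egl3) and 1 (wer with myb23) passed. There, root hair wall in the arrays labelled cpc ttg2 against cpc (-0.57, adjusted p = 0.225) and root hair growth against ttg2 (-0.61, 0.119) did not pass.

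With the class of the sample number as a block, counts were 1081 (wer with cpc), 1298 (arrays labelled cpc ttg2 with cpc), 244 (gl3 with egl3, 135 higher and 109 lower) and 0 (wer with myb23). Root hair wall did not pass in the arrays labelled cpc ttg2 against cpc (-0.48, 0.0539) and in gl3 against egl3 (0.27, 0.0661), and MYB23 in myb23 did (-0.72, 0.0244). With the mitochondrial covariate, counts were 1124 (wer with cpc) and 1482 (cpc with try), root hair wall (-0.20, 0.636) and growth (-0.44, 0.115) did not pass in the arrays labelled cpc ttg2 against cpc and against ttg2, r of the cpc differences was 0.14 (wer) and 0.21 (try), and MYB23 passed (-0.70, 0.0249). With this covariate, stele in the arrays labelled cpc ttg2 against cpc (0.28, 0.169) and against ttg2 (0.27, 0.145), and ground tissue (0.30, 0.112) and iron deficiency (0.21, 0.0732) in gl3 against egl3 did not pass, and wound, touch and jasmonate genes in wer against myb23 did (-0.23, 0.0381). Without the 4 arrays, counts were 279 (wer with cpc), 1126 (arrays labelled cpc ttg2 with ttg2), 305 (cpc with try) and 3496 (F test), root hair wall was 0.18 (0.137) in gl3 against egl3 and 0.53 (0.000981) in cpc against try, r was 0.21 and 0.35, and EGL3 (1.01, 0.0312) and MYB23 (-0.66, 0.0358) passed. Ground tissue (0.29, 0.0648) and flavonoid genes (0.18, 0.0938) in gl3 against egl3, cell cycle in cpc against try (-0.18, 0.386) and heat shock in wer against myb23 (0.33, 0.0594) did not pass there. Cell cycle in wer against cpc (-0.52, 1.48e-05) and gl3 against egl3 (-0.56, 9.35e-06), stele in gl3 against egl3 (0.22, 0.0442), ground tissue in cpc against try (0.45, 0.0089) and wound, touch and jasmonate genes in wer against myb23 (-0.22, 0.038) passed.

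Array weights did not converge and gave try replicate 3 a weight of 54.9. They gave 2282 (wer with cpc), 5353 (arrays labelled cpc ttg2 with cpc), 11510 (cpc with try), 11 (wer with myb23) and 15970 genes (F test), and TTG2 (-0.37, 0.0273), EGL3 (0.97, 0.00707) and MYB23 (-0.56, 0.00707) passed. Gene-by-gene weights, 6.18 for that array, gave 1986, 5404, 8402, 9 and 12021, with TTG2 at -0.38 (0.0287), EGL3 at 0.94 (0.00986) and MYB23 at -0.56 (0.00908). With an estimated correlation, 0 of 84 lists passed, among them root hair growth and wall in wer with cpc (means 1.37 and 1.05, adjusted p = 0.368 and 0.521), wall in the arrays labelled cpc ttg2 with cpc (-0.57, 0.778), growth and wall against ttg2 (-0.61 and -1.04, 0.757 and 0.579), in gl3 with egl3 (0.51 and 0.46, 0.579 and 0.647) and in wer with myb23 (0.46 and 0.54, 0.568 and 0.579).

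Leaving out 1 array at a time, counts ran from 221 (without cpc replicate 3) to 797 (wer with cpc), 643 to 2981 (arrays labelled cpc ttg2 with cpc), 822 to 1903 (with ttg2), 81 to 185 (gl3 with egl3), 230 to 676 (cpc with try), 0 to 43 (wer with myb23) and 3588 to 6547 (F test). Root hair growth ran from -0.19 to 0.57 in the arrays labelled cpc ttg2 with cpc, -0.92 to -0.18 with ttg2 and -0.55 to 0.086 in cpc with try. Root hair wall ran from -0.96 to -0.053 in the arrays labelled cpc ttg2 with cpc, 0.18 to 0.65 in gl3 with egl3 and -0.16 to 0.53 in cpc with try. The r of the cpc differences ran from 0.19 to 0.41 (wer) and 0.31 to 0.52 (try), EGL3 from 0.31 to 1.15, and TTG2 over both lines from -0.51 to -0.26.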

Other observations

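The test of a shared effect of ttg2-1 was chosen after the result was seen, and the splits of the arrays were not.

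ETC1, a single-repeat MYB gene of the patterning network, was higher wherever a line carried the ttg2 label. It was 1.99 higher in ttg2 than in the 5 lines with intact CPC and TTG2, and 1.68 higher in the arrays labelled cpc ttg2 than in cpc (adjusted p = 0.024, limma), which ended without any 1 array except cpc replicate 3. These differences were not found to differ from each other (-0.31 ± 0.56, SE, adjusted p = 0.907 over the patterning list). MYB23 was 0.19 in the former and 1.55 in the latter (difference 1.36, adjusted p = 0.0666).

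Among the 117 genes called the same way in cpc minus wer and in the arrays labelled cpc ttg2 minus ttg2, 4 were picked after their values were seen, and no group of genes was tested for an excess there. ROT3 (AT4G36380), a brassinosteroid hydroxylase, was at 0.92 and 1.18, and the kinase gene BSK1 (AT4G35230) at 1.02 and 1.03. The danger peptide receptor gene PEPR2 (AT1G17750) was at 1.28 and 1.17, and SOBIR1 (AT2G31880), a co-receptor of immune receptors, at 0.95 and 0.83.

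A hypothesis was that ETC1 and other genes move alike because the arrays labelled cpc ttg2 share an effect of ttg2-1 with ttg2. Of 38 genes called in ttg2 minus 5 lines, with TTG2 left out, 31 had the same direction in the arrays labelled cpc ttg2 minus cpc (81.6%, exact Clopper-Pearson 95% interval 65.7 to 92.3). With the mitochondrial covariate, it was 87 of 165 genes (52.7%, 44.8 to 60.5). The hypothesis failed the criterion set for it, a lower bound above 50% in both fits. That criterion cannot exclude it, because a weak shared effect would also give an interval on both sides of 50%, and because the covariate also changed which genes were called. It stays undecided, and genes are not independent, so the intervals are too narrow.

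For each comparison the 6 arrays were also split in the other ways into 3 and 3, which makes 10 splits, too few for a share under 0.05. In wer with cpc, 1 split, the real one, gave 654 genes, and the highest other gave 0. In the arrays labelled cpc ttg2 with cpc, the real split gave 1950 and the highest other 845. With ttg2, the real split gave 2185 and the highest other 1. In gl3 with egl3 these were 141 and 3, and in wer with myb23 4 and 0. In cpc with try, 2 splits gave at least the real 504 genes, since cpc replicate 1 and try replicates 2 and 3 against the rest gave 779. This split, and the one with 845 (cpc replicates 1 and 2 and cpc ttg2 replicate 1 against the rest), follow the order of the arrays on the first principal component, which points to a structure of the arrays besides the lines. For the 8 lines, the real grouping gave 5786 genes and the highest of the others among 100 groupings 691. Only 1 grouping of 100, the real one, was as large, which is the smallest share possible here and argues against chance. It does not separate the lines from a batch that follows them.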
